A study of Mus musculus with 36 samples.

How the data were processed

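Hippocampal tissue of 3-month-old female mice was assayed by RNA sequencing and by chromatin immunoprecipitation sequencing (ChIP-seq) of 7 histone marks. CK-p25 mice are a transgenic model in which p25, a truncated activator of the kinase Cdk5, is induced in the adult forebrain and neurons are then lost. CKp25 animals were compared with control littermates, labelled CK, at 2 and 6 weeks after induction. The 36 samples were 4 RNA samples, 28 ChIP samples with 1 peak list each, and 4 whole cell extract samples, which serve as the background of the ChIP and had no file of their own here. Each RNA sample held 3 libraries, which are named below as in the labels, by group, time and number (CK_2wk_4520, for example). The labels do not say that these numbers are animals, so p-values measure the spread between libraries, which may be technical. The labels give the same age, 3 months, at both times, which may be that at induction or at collection. Time since induction, any difference in age at collection and any batch shared by a time cannot be separated in this design.

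The RNA values were deposited as raw read counts per Ensembl gene, in 1 table with 12 columns. Per the submitters' processing notes, Bowtie, Picard, HTSeq 0.6.1 and MACS2 were used with the mouse builds NCBIM37 and mm9. Per the labels' protocols, the RNA libraries were made with a stranded total RNA kit after removal of ribosomal RNA. The strand setting of the counting is not given in the sources used here, so a gene and an antisense partner may share reads. Reads that aligned to more than 1 place were set aside in the deposited counts, so members of near-identical families (MHC class I genes, interferon-induced paralogs, hemoglobins) are undercounted to an unknown extent. The table closes with 5 entries that name no gene, which were kept out of library sizes and tests. Reads outside annotated features made up 38.1 to 46.9% of a library's total, unaligned reads 6.13 to 11.1%, reads with several alignments 6.81 to 14.3%, ambiguous reads 0.137 to 0.165%, and reads of low alignment quality 0%. At 6 weeks, reads with several alignments made up 6.86 to 9.52% in CK and 11.5 to 13.9% in CKp25, and reads outside features 41.6 to 46.1% and 38.1 to 40.2%, with no overlap. At 2 weeks CK_2wk_4520 and CKp25_2wk_4518 stood apart from the other 4 libraries, with 7.15 and 6.81% of reads aligned to several places against 12.2 to 14.3%, and 44.9 and 46.9% outside features against 38.3 to 39.7%. The remaining gene counts were 5029996 to 6450140 per library. The table gives no gene names. The ID and symbol table supplied with the data named 32919 of the 37991 genes (86.6%) and 97.3% of those tested.

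The peak lists were deposited as 1 list per mark and group, each called against a whole cell extract, and the sources used here do not say whether animals were pooled. Fold enrichment over the extract at each peak and the -log10 of its p-value are the authors' own deposited values. They were used only to rank or filter peaks within a list. The deposited -log10 p-values were all above 2. Coordinates are those of mm9, 1-based. No annotation of that build was used, so no gene is named at a peak and the planned comparison of marks at promoters was not made.

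Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passing filterByExpr (14457) were scaled with trimmed mean of M-values (TMM) factors and fitted with quasi-likelihood models. All 12 libraries entered a fit with 4 group means, so that the groups shared 1 estimate of the spread. Contrasts were CKp25 against CK at each time, the difference of those effects between times, and 6 against 2 weeks within each genotype. A model of genotype plus time gave the genotype effect over both times. Adjusted p-values are Benjamini-Hochberg values of edgeR's quasi-likelihood test, and genes passing 0.05 are called higher or lower. Fold changes are log2, with standard errors (SE). Levels are CPM, counts divided by the TMM-scaled library size, as mean ± SD of 3 libraries. Libraries of a group differed by a chi-square of 1.48 to 9.15 per gene, so none was a copy of another. The closest pairs were CK_2wk_4891 and CK_2wk_4893 (1.48) and CKp25_2wk_4890 and CKp25_2wk_4894 (2.27). Pairs with CK_2wk_4520 or CKp25_2wk_4518 differed by 5.87 to 9.15, so the 3 libraries of a 2-week group were not evenly apart.

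Before the data were examined, the groups, contrasts, tests, 32 gene lists, alternatives and the rule for named genes were fixed. Of 452 list entries, 447 matched a symbol, 5 of them through synonyms, and 420 were tested. The 5 synonym matches used a RefSeq table of another build (GRCm38), for names alone. Lists with at least 3 tested members were tested with camera (limma 3.58.1, preset correlation 0.01), with Benjamini-Hochberg adjustment over lists within a contrast. Camera with an estimated correlation and fry were run beside it. Camera compares a list with the other genes, and fry asks whether a list moves on balance in 1 direction. The rule named, at 2 and at 6 weeks, Cdk5r1 (the gene from which p25 derives) and the 6 highest and 6 lowest fold changes among called genes with a mean of at least 1 CPM in either group and no overlap between groups. It also named up to 3 called members of each list by smallest adjusted p, of which the text prints 1 to 3. For the difference between times it named 5 genes in each direction, and for the other contrasts 3. Genes without a symbol were skipped, and some genes that the rule named are not reported here. Any other gene printed was chosen after its values were seen.

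Where a gene had 0 counts over the 3 libraries of a group, the fold is a lower bound against a floor of 3 counts over the group. With 1 to 3 counts, the ratio is given with a 95% counting interval. Intervals and floors cover counting error only. Medians of lists that hold such zero-count genes did not move when these were set to their bounds.

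Peak lists were compared with bedtools 2.31.1, as the share of peaks in either list that overlapped the other by at least 1 bp. With 1 list per group there is no replicate check and no p-value. Peaks of a mark were also merged into regions over its 4 lists, and regions with a peak of -log10 p of at least 5 in both CKp25 lists and no peak in either CK list were counted, with the reverse and the 4 other divisions of 2 lists against 2. The limit of 5 was chosen after the data were seen.

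The scripts were tested on simulated data with known changes, drawn from the real genes' means. Counts were simulated for 14457 genes, and gene numbers in brackets are those that passed the filter again. Shares are of the changed genes among these, 98 to 100 at each fold. In the real data 19.6% of genes were called at 2 weeks and 33.3% at 6 weeks, so recovery and false calls may differ there. At 2 weeks (14283 genes), 74.8% of 2-fold and 99.0% of 4-fold changes were recovered. At 6 weeks (14270 genes) the shares were 75.5% and 99.0%. For the difference between times (14283 genes) they were 65.7% and 86.7%, for time in CKp25 (14283 genes) 79.8% and 95.9%, for time in CK (14252 genes) 80.8% and 91.8%, and for genotype over both times (14270 genes) 91.8% and 100%. False calls made up 5.03 to 11.7% of calls across these contrasts.

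Alternatives were other scalings, other filters on low counts, DESeq2 1.42.0, limma-voom, stricter thresholds, only the compared groups, and leaving out each library in turn. For peaks they were an overlap of 50% of the peak and equal numbers of peaks per list. A block on nearest library numbers, covariates for choroid plexus genes and for the share of reads with several alignments, leaving out CK_2wk_4520 and CKp25_2wk_4518 together, counts thinned at random to 50% and p-value limits for peaks were added after the data were seen. Other splits of the libraries were also fitted.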

Results

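Gene expression was compared between CKp25 and CK hippocampus in 12 RNA libraries, 3 per group. At 2 weeks, CK libraries CK_2wk_4520, CK_2wk_4891 and CK_2wk_4893 held 6010601, 5062422 and 5194645 gene counts, and CKp25 libraries CKp25_2wk_4518, CKp25_2wk_4890 and CKp25_2wk_4894 held 6450140, 5242539 and 5832708. At 6 weeks, CK libraries CK_6wk_3936, CK_6wk_3938 and CK_6wk_4009 held 5037328, 5109241 and 5817006, and CKp25 libraries CKp25_6wk_3937, CKp25_6wk_3940 and CKp25_6wk_4008 held 5029996, 6229896 and 5421887. Genotype separated the libraries along the first principal component of the 1000 genes used, which held 74.6% of the variance. The second component held 9.78% and followed genes of the choroid plexus, the tissue that secretes cerebrospinal fluid. Ttr, which encodes the transthyretin made there, lay between 6.44 and 2244 CPM, with high and low libraries in each group, and none of the 10 choroid plexus genes tested was called at either time.

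The first comparison asked which genes differed between CKp25 and CK 2 weeks after p25 induction. Genes of microglia, complement, MHC class I, the interferon response, cytokines, cell division and DNA repair were higher in CKp25, and genes of cholesterol synthesis were lower. These 9 list calls by camera held with an estimated correlation, at an adjusted p of 0.0251 to 0.0414. Camera also called genes of synaptic vesicles, glutamate receptors and voltage-gated channels lower, and these calls were lost with an estimated correlation (adjusted p = 0.208, 0.256 and 0.256). By fry, 16 of camera's 17 list calls at 2 weeks held and 1 was lost (adjusted p = 0.054). Of 14457 genes tested, 1678 were higher and 1155 lower by edgeR's quasi-likelihood test. The rises were larger than the falls, with a median log2 fold change of 1.21 among higher and -0.35 among lower genes. A change of at least 2-fold was seen in 982 higher and 11 lower genes. Cdk5r1 (ENSMUSG00000048895), the mouse gene for the p35 activator from which p25 is cut, fell from 194 ± 4.49 to 153 ± 4.81 CPM (SD, n = 3). The labels do not give the species of the transgene, so this level does not check the genotype labels.

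All 12 homeostatic microglia genes were higher at 2 weeks (12 adjusted over the list alone), with a median log2 fold change of 1.63. Csf1r, the receptor on which microglia depend to survive, rose from 66.8 ± 4.54 to 238 ± 26.4 CPM. Among genes of activated phagocytic microglia, 19 of 20 rose (19 adjusted over the list alone; median 2.45), including the lysosomal protease Ctsd, from 234 ± 4.17 to 1268 ± 218 CPM. Complement genes rose in 11 of 12 cases (12 adjusted over the list alone; median 2.87). C1qa, a subunit of the first complement component, went from 22.4 ± 2.69 to 178 ± 33.8 CPM. Camera's adjusted p was 7.46e-15, 1.60e-18 and 1.47e-13 for these 3 lists, and 0.0414, 0.0315 and 0.0315 with an estimated correlation.

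The type I interferon list rose as a whole, with 24 of 24 members higher (24 adjusted over the list alone) and a median log2 fold change of 4.48. Irf7, a transcription factor that amplifies interferon output, rose from 1.23 ± 0.617 to 59.4 ± 4.74 CPM. All 13 MHC class I and antigen processing genes were higher (13 adjusted over the list alone; median 3.06), among them B2m (ENSMUSG00000060802), the invariant chain of MHC class I, from 43.0 ± 2.81 to 339 ± 15.4 CPM. Cytokine, chemokine and NF-kB target genes were higher in 14 of 17 cases (14 adjusted over the list alone; median 2.56). Camera's adjusted p was 1.78e-34, 3.61e-16 and 9.36e-14, and 0.0251, 0.0315 and 0.0315 with an estimated correlation. MHC class II genes were called in 3 of 7 cases (7 adjusted over the list alone; median 2.79), with a camera adjusted p of 0.00393, or an adjusted p of 0.409 with an estimated correlation. Cd74, the class II chaperone, varied between CKp25 libraries (20.3 ± 21.3 CPM against 2.15 ± 0.987 in CK). Its call was lost without library CK_2wk_4891, CK_2wk_4893 or CKp25_2wk_4890, at log2 fold changes of 3.08, 2.86 and 1.83, and by limma-voom (2.63). Of reactive astrocyte genes, 11 of 17 were higher (14 adjusted over the list alone; median 2.01), with a camera adjusted p of 2.91e-11 and an adjusted p of 0.0533 with an estimated correlation. Gfap, the astrocyte intermediate filament, rose from 202 ± 10.8 to 1737 ± 118 CPM. Of general astrocyte genes 4 of 12 were higher and 1 lower (4 and 1 adjusted over the list alone; median 0.17; camera adjusted p = 0.0935), a list that was called without library CKp25_2wk_4894 (0.18).

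Cell cycle genes were higher in 25 of 26 cases at 2 weeks (25 adjusted over the list alone), with a median log2 fold change of 3.46 and a camera adjusted p of 5.16e-29, or an adjusted p of 0.031 with an estimated correlation. Mki67, which encodes the proliferation marker Ki-67, rose from 2.25 ± 0.421 to 152 ± 44.8 CPM, and the replicative helicase subunit Mcm6 from 11.4 ± 2.20 to 72.7 ± 10.1. Of DNA repair genes, 14 of 16 rose (14 adjusted over the list alone; median 1.72), with a camera adjusted p of 9.36e-14, or an adjusted p of 0.0251 with an estimated correlation. Brca1, which acts in homologous recombination, reached 35.9 ± 9.58 CPM from 1.99 ± 0.583. The p53 and DNA damage list had 11 of 19 members higher and 1 lower (12 and 1 adjusted over the list alone; median 0.68). Its camera adjusted p was 2.88e-06, and its adjusted p was 0.0533 with an estimated correlation. Members that rose included the cell cycle inhibitor Cdkn1a, from 1.93 ± 0.795 to 14.7 ± 3.84 CPM, and the apoptosis inducers Pmaip1 and Bbc3, at log2 fold changes of 4.22 ± 0.35 and 2.29 ± 0.26 (SE).

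Synaptic vesicle genes were lower in 13 of 18 cases at 2 weeks (18 adjusted over the list alone; median -0.34), glutamate receptor and postsynaptic genes in 15 of 20 (17 adjusted over the list alone; median -0.32), and voltage-gated channel genes in 11 of 16 (12 adjusted over the list alone; median -0.32). Camera's adjusted p was 4.51e-08, 7.64e-08 and 1.09e-05 for the 3 lists, and these calls were lost with an estimated correlation, at an adjusted p of 0.208, 0.256 and 0.256. Slc17a7, the vesicular glutamate transporter of excitatory neurons, fell from 801 ± 49.3 to 549 ± 16.0 CPM. Camk2a, a kinase of the postsynaptic density, fell from 1517 ± 70.9 to 1004 ± 107 CPM. CA pyramidal neuron genes were lower in 3 of 8 cases (4 adjusted over the list alone; median -0.21), at a camera adjusted p of 0.0427 and an adjusted p of 0.256 with an estimated correlation. That list was not called without library CK_2wk_4891, CKp25_2wk_4894 or CK_6wk_4009 (medians -0.21, -0.17 and -0.21). Dentate granule neuron genes were lower in 1 of 8 cases (1 adjusted over the list alone; median -0.25; camera adjusted p = 0.0686), a list that was called without library CKp25_2wk_4518 (-0.34). Cholesterol synthesis genes fell in 9 of 17 cases (13 adjusted over the list alone; median -0.44), with a camera adjusted p of 3.37e-07, or an adjusted p of 0.0315 with an estimated correlation.

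The highest named fold changes at 2 weeks belonged to inflammatory and mitotic genes that were near 0 in CK. Cxcl10 (ENSMUSG00000034855), a chemokine induced by interferon, had 2 counts over the CK libraries and 1086 over the CKp25 libraries, a ratio of 466 with a counting interval of 129 to 3854. Cst7, a cysteine protease inhibitor of activated microglia, had a ratio of 221 (60.9 to 1830). Timp1, Ccl3, Ccl2 and the mitotic cohesin protector Sgo1 had no counts in CK and were at least 22.3-fold, 22.0-fold, 21.8-fold and 15.7-fold higher. The lowest were Erich5 (-1.63), Igfn1 (-1.47), Vmn2r84 (-1.42), C230034O21Rik (-1.28), Gm3571 (-1.14) and the potassium channel gene Kcnk4 (-1.14), all with means under 6 CPM. None of these 6 calls held in every fit that left out a library. DESeq2 did not call Vmn2r84 (adjusted p = 0.0959), C230034O21Rik (0.063) or Gm3571 (0.156), and limma-voom did not call Igfn1 (0.0787). With counts thinned to 50%, Igfn1 and Kcnk4 were not called (-1.39, -1.29), and with CK_2wk_4520 and CKp25_2wk_4518 both left out, Vmn2r84, C230034O21Rik and Gm3571 were not (-1.01, -1.03, -1.16). Erich5 was not called without CK_2wk_4891 or CKp25_2wk_4894 (-1.50, -1.35), Igfn1 without CK_2wk_4891, CK_2wk_4893, CKp25_2wk_4890 or CKp25_2wk_4894 (-1.36, -1.25, -1.56, -1.24), and Kcnk4 without CK_2wk_4893, CKp25_2wk_4518 or CKp25_2wk_4890 (-0.80, -1.0, -1.07). C230034O21Rik was lost without CK_2wk_4520, CK_2wk_4891, CKp25_2wk_4518 or CKp25_2wk_4890 (-1.22, -1.09, -1.10, -1.19), Gm3571 without CK_2wk_4520, CK_2wk_4891, CK_2wk_4893, CKp25_2wk_4518 or CKp25_2wk_4894 (-1.06, -1.20, -1.16, -1.23, -0.89). Vmn2r84 was lost without any 2-week library (CK_2wk_4520, CK_2wk_4891, CK_2wk_4893, CKp25_2wk_4518, CKp25_2wk_4890, CKp25_2wk_4894, at -1.49, -1.50, -1.29, -0.95, -1.68, -1.73) without CK_6wk_4009 or CKp25_6wk_4008 (-1.43, -1.42), and with choroid plexus genes as a covariate (-1.35).

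Myelin, endothelial and pericyte genes were not called as lists at 2 weeks (camera adjusted p = 0.66, 0.286 and 0.363), with 1 of 12, 0 of 11 and 0 of 12 members called (1, 0 and 0 adjusted over the list alone; medians 0.12, 0.19 and 0.06). The pericyte list was called higher without library CK_2wk_4520 (0.56). The total of 2833 genes called at 2 weeks fell to 1806 without library CKp25_2wk_4894. The 1155 lower genes became 646 without CK_2wk_4891, 621 without CK_2wk_4893 and 476 without CKp25_2wk_4894, when 68.5, 68.7 and 73.6% of calls were higher, and 648 with counts thinned to 50%.

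**Figure D1:**
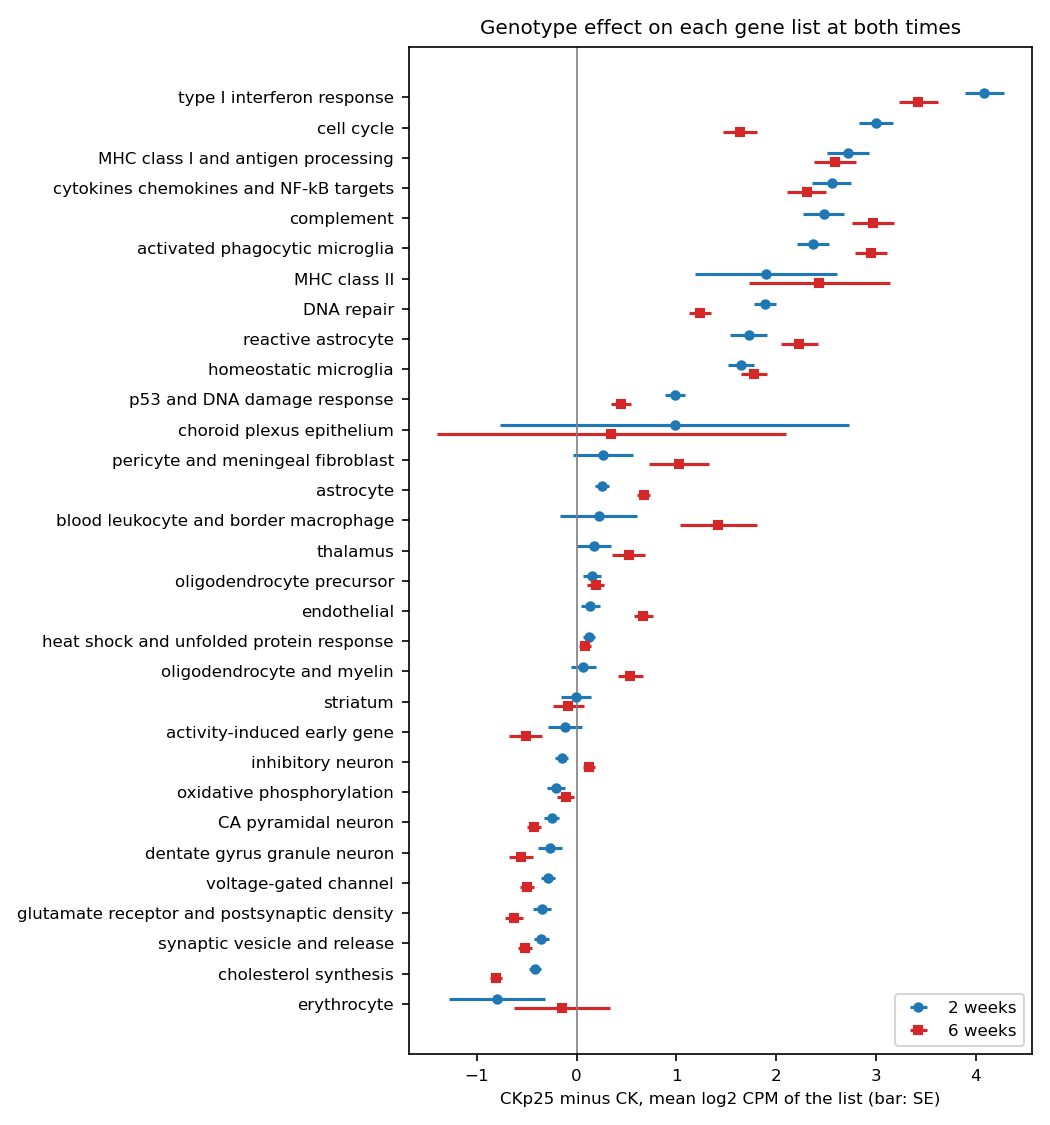
Each list's genotype effect is plotted as CKp25 minus CK in mean log2 CPM over its tested members, at 2 weeks (circles) and 6 weeks (squares), with SE bars from 12 libraries. Interferon, immune and cell cycle lists lie right of 0 at both times, with a cell cycle effect of 3.00 at 2 weeks and 1.64 at 6 weeks, and synaptic and cholesterol lists lie left of it.

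The comparison of CKp25 with CK at 6 weeks asked which genes differed at the later time. Camera called genes of microglia, the interferon response, antigen presentation and the cell cycle higher, along with those of astrocytes, myelin and blood vessels. It called genes of excitatory synapses, granule and pyramidal neurons and cholesterol synthesis lower. None of its 24 list calls at 6 weeks held with an estimated correlation, at an adjusted p of 0.0559 to 0.564, and 23 of the 24 held by fry. Of 14457 genes, 2614 were higher and 2197 lower by edgeR's test, with median log2 fold changes of 0.93 and -0.41. A change of at least 2-fold was seen in 1209 higher and 50 lower genes. Cdk5r1 was at 129 ± 14.6 CPM in CKp25 and 183 ± 4.06 in CK. Beside these gene groups, the share of reads with several alignments separated the genotypes at 6 weeks, at 6.86 to 9.52% in CK and 11.5 to 13.9% in CKp25. So did reads outside annotated features, at 41.6 to 46.1% and 38.1 to 40.2%. With the first of these shares as a covariate, 2249 genes were higher and 1722 lower, 3478 of them among the 4811 called without it.

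At 6 weeks, homeostatic microglia genes were higher in 12 of 12 cases (12 adjusted over the list alone; median 1.94), activated microglia genes in 19 of 20 (19 adjusted over the list alone; median 2.99), and complement genes in 12 of 12 (12 adjusted over the list alone; median 3.27). Camera's calls of these 3 lists did not hold with an estimated correlation, at an adjusted p of 0.0725, 0.0609 and 0.0609. Trem2, a lipid-sensing receptor of microglia, rose from 5.88 ± 1.60 to 67.7 ± 12.3 CPM, and the complement gene C4b from 45.0 ± 5.25 to 743 ± 157. Interferon genes were higher in 24 of 24 cases (24 adjusted over the list alone; median 4.02), MHC class I genes in 13 of 13 (13 adjusted over the list alone; median 3.05), and cytokine and NF-kB genes in 15 of 17 (15 adjusted over the list alone; median 2.51). These 3 did not hold either, at an adjusted p of 0.0609, 0.0658 and 0.0658 with an estimated correlation. With the preset correlation camera's adjusted p was 1.66e-22 to 3.80e-11 for the 6 lists. Irf7 rose from 1.65 ± 0.379 to 36.9 ± 8.51 CPM. MHC class II genes were higher in 6 of 7 cases (6 adjusted over the list alone; median 3.51), with a camera adjusted p of 0.00894, or an adjusted p of 0.334 with an estimated correlation. Cd74 reached 76.4 ± 48.6 CPM, against 3.47 ± 1.79 in CK.

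Reactive astrocyte genes rose in 15 of 17 cases at 6 weeks (16 adjusted over the list alone; median 2.36), general astrocyte genes in 11 of 12 (11 adjusted over the list alone; median 0.65), and oligodendrocyte and myelin genes in 9 of 12 (9 adjusted over the list alone; median 0.55). These calls were lost with an estimated correlation, at an adjusted p of 0.0658, 0.119 and 0.266. Gfap rose from 211 ± 17.8 to 2732 ± 702 CPM, the water channel Aqp4 from 137 ± 15.6 to 495 ± 135, and the myelin adhesion protein Mag from 124 ± 10.3 to 193 ± 20.8. Endothelial genes were higher in 11 of 11 cases (11 adjusted over the list alone; median 0.70), with an adjusted p of 0.129 with an estimated correlation. Among them was Tek, the receptor for angiopoietins, at a log2 fold change of 0.80 ± 0.15 (SE). Pericyte and meningeal fibroblast genes rose in 9 of 12 cases (10 adjusted over the list alone; median 1.00), including the type I collagen genes Col1a1 (1.65 ± 0.28) and Col1a2 (1.79 ± 0.35). Its adjusted p was 0.26 with an estimated correlation. With the preset correlation camera's adjusted p was 4.32e-12, 3.24e-07, 0.000272, 2.20e-05 and 0.000567 for these 5 lists. In mean log2 CPM over members they rose by 2.23 ± 0.187, 0.671 ± 0.0689, 0.538 ± 0.125, 0.670 ± 0.0935 and 1.03 ± 0.297 (SE). A lower share of neurons would raise glial and vessel lists alike. Whether it raised these lists at 6 weeks was not tested.

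Cell cycle genes were higher in 22 of 26 cases at 6 weeks (23 adjusted over the list alone; median 1.61), with Mki67 at 26.1 ± 6.60 CPM against 2.11 ± 0.424 in CK. DNA repair genes were higher in 11 of 16 (13 adjusted over the list alone; median 1.14). In the p53 list 7 of 19 were higher and 1 lower (7 and 1 adjusted over the list alone; median 0.24). Camera's adjusted p was 3.26e-12, 2.97e-07 and 0.0498, and these calls were lost with an estimated correlation, at an adjusted p of 0.0871, 0.0609 and 0.329. The p53 call was also lost without library CK_2wk_4520, CK_2wk_4891, CKp25_2wk_4518, CK_6wk_3936, CK_6wk_3938, CKp25_6wk_3937, CKp25_6wk_3940 or CKp25_6wk_4008 (medians 0.24, 0.24, 0.23, 0.22, 0.23, 0.26, 0.27 and 0.23).

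Synaptic vesicle genes were lower in 16 of 18 cases at 6 weeks (16 adjusted over the list alone; median -0.50), glutamate receptor and postsynaptic genes in 20 of 20 (20 adjusted over the list alone; median -0.59), and voltage-gated channel genes in 15 of 16 (16 adjusted over the list alone; median -0.53). With an estimated correlation these 3 calls were lost, at an adjusted p of 0.131, 0.129 and 0.129. Camk2a fell from 1444 ± 160 to 739 ± 112 CPM, and Grin2a, an NMDA receptor subunit, from 421 ± 48.5 to 235 ± 35.3. Dentate granule neuron genes fell in 5 of 8 cases (6 adjusted over the list alone; median -0.65), CA pyramidal genes in 5 of 8 (5 adjusted over the list alone; median -0.40), and activity-induced early genes in 9 of 16 (9 adjusted over the list alone; median -0.46). These calls were also lost, at an adjusted p of 0.219, 0.154 and 0.266 with an estimated correlation. Calb1, a calcium buffer of granule cells, fell from 69.6 ± 2.61 to 38.9 ± 1.52 CPM, and the synaptic immediate early gene Arc from 189 ± 23.3 to 83.6 ± 21.5. With the preset correlation camera's adjusted p was 3.08e-09, 4.89e-12, 1.28e-08, 0.00526, 0.0125 and 0.00125 for these 6 lists. Cholesterol synthesis genes were lower in 15 of 17 cases (16 adjusted over the list alone; median -0.78), at a camera adjusted p of 2.19e-11 and an adjusted p of 0.0559 with an estimated correlation. Sqle, the squalene epoxidase of this pathway, fell from 51.4 ± 5.29 to 22.0 ± 2.49 CPM.

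The highest named fold changes at 6 weeks were in genes near 0 in CK. Clec7a, a pattern recognition receptor of phagocytes, had a ratio of 578 with a counting interval of 103.4 to 22880, Cst7 of 437 (78.0 to 17280) and Cxcl10 of 387 (69.1 to 15330). Zbp1, a sensor of nucleic acids, and the interferon-induced Ifi206 were at least 31.1-fold and 23.3-fold higher. Itgax, an integrin of activated microglia, rose from 0.251 ± 0.219 to 52.2 ± 17.3 CPM. The lowest were Col6a4 (-2.20 ± 0.48, SE), Adamts18 (-2.13 ± 0.52), Gm13502 (-1.58 ± 0.25), the granule cell gene C1ql2 (-1.50 ± 0.22), Krt2 (-1.50 ± 0.34) and Gm9754 (-1.48 ± 0.48). Gm9754 was not called by DESeq2 (-1.50) or without library CK_6wk_3938, CK_6wk_4009, CKp25_6wk_3937 or CKp25_6wk_3940 (-1.28, -1.39, -1.19, -1.46), nor with reads of several alignments as a covariate (-1.05). The total of 4811 called genes moved by less than 1.5 times, as did the higher and lower counts, in every other fit that kept the threshold and set no minimum fold.

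Both times were compared to see whether the effects went the same way; the comparisons share no library. Of the genes called at 2 weeks, 2131 (75.2%) were called in the same direction at 6 weeks. Genes higher at both times numbered 1271, where independent lists would share 303, and genes lower at both times numbered 860, where they would share 176. In 13 genes the calls were opposite, among them Col6a4, at log2 fold changes of 2.23 ± 0.49 and -2.20 ± 0.48 (SE). Across all tested genes, which are not independent replicates, the fold changes had a Pearson r of 0.809 and a Spearman rho of 0.644.

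The difference of the CKp25 effect between 6 and 2 weeks was then tested directly. The effect on the apolipoprotein genes Apoe and Clu was higher at 6 weeks, and that on the apoptosis gene Bbc3 was lower. Apoe (ENSMUSG00000002985), the main brain apolipoprotein, was at 672 ± 23.6 and 1029 ± 94.6 CPM in CK and CKp25 at 2 weeks, and at 683 ± 53.9 and 2732 ± 651 at 6 weeks. Its effect was greater by 1.39 ± 0.18 log2 at 6 weeks (SE; edgeR adjusted p = 0.00263). Clu, the apolipoprotein clusterin, differed by 1.10 ± 0.14, Igfbp5, a carrier of insulin-like growth factors, by 1.38 ± 0.15, Ccdc3 by 1.53 ± 0.21, and the antioxidant enzyme Prdx6 by 1.00 ± 0.14. Bbc3, the p53 target Puma, was at 14.4 ± 4.60 CPM against 2.93 ± 0.471 in CK at 2 weeks, and at 4.74 ± 1.12 against 4.64 ± 0.435 at 6 weeks. Its difference was -2.27 ± 0.39 (edgeR adjusted p = 0.0142). Plk5 differed by -1.78 ± 0.24, Col6a4, to which DESeq2 gave no adjusted p, by -4.42 ± 0.68, Tex15 by -2.08 ± 0.33 and the motor gene Myo5b by -0.82 ± 0.14.

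By list, 19 of those tested differed between the times by camera. None of these calls held with an estimated correlation, at an adjusted p of 0.117 to 0.522. By fry 7 of them held and 12 were lost, at an adjusted p of 0.101 to 0.274, among them activated microglia (0.136), complement (0.186), interferon (0.129) and myelin genes (0.101). Cell cycle genes had a median difference of -1.36 with 2 of 26 members called (14 adjusted over the list alone), DNA repair genes -0.64 with 0 of 16 (4 adjusted over the list alone), and cholesterol synthesis genes -0.37 with 1 of 17 (6 adjusted over the list alone). With an estimated correlation the adjusted p was 0.117 for each of the 3, and fry's adjusted p was 0.00683, 0.0129 and 0.00683. The p53 list (median -0.47, 2 lower of 19; 6 lower and 1 higher adjusted over the list alone) had an adjusted p of 0.242 with an estimated correlation and of 0.0353 by fry. Astrocyte genes had a median difference of 0.45 with 3 of 12 called (7 adjusted over the list alone), endothelial genes 0.58 with 0 of 11 (8 adjusted over the list alone), and inhibitory neuron genes 0.32 with 1 of 13 (2 adjusted over the list alone). Their adjusted p with an estimated correlation was 0.2, 0.2 and 0.279, and fry's was 0.0129, 0.0336 and 0.0465.

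In total 54 genes had a higher and 26 a lower CKp25 effect at 6 weeks. This count of 80 was set by single libraries: it was 28 without CK_2wk_4891, 47 without CK_2wk_4893, 24 without CKp25_2wk_4894, 47 without CK_6wk_3938, 47 without CKp25_6wk_3937, 204 without CKp25_6wk_3940 and 50 without CKp25_6wk_4008. DESeq2 called 219, 693 were called with no filter on low counts, 302 with choroid plexus genes and 301 with the share of reads with several alignments as a covariate, and 544 with nearest library numbers as a block. The 26 lower genes became 17 without CKp25_2wk_4890, 16 without CK_6wk_3936 and 15 by limma-voom, fits in which the total stayed within 1.5 times.

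**Figure D2:**
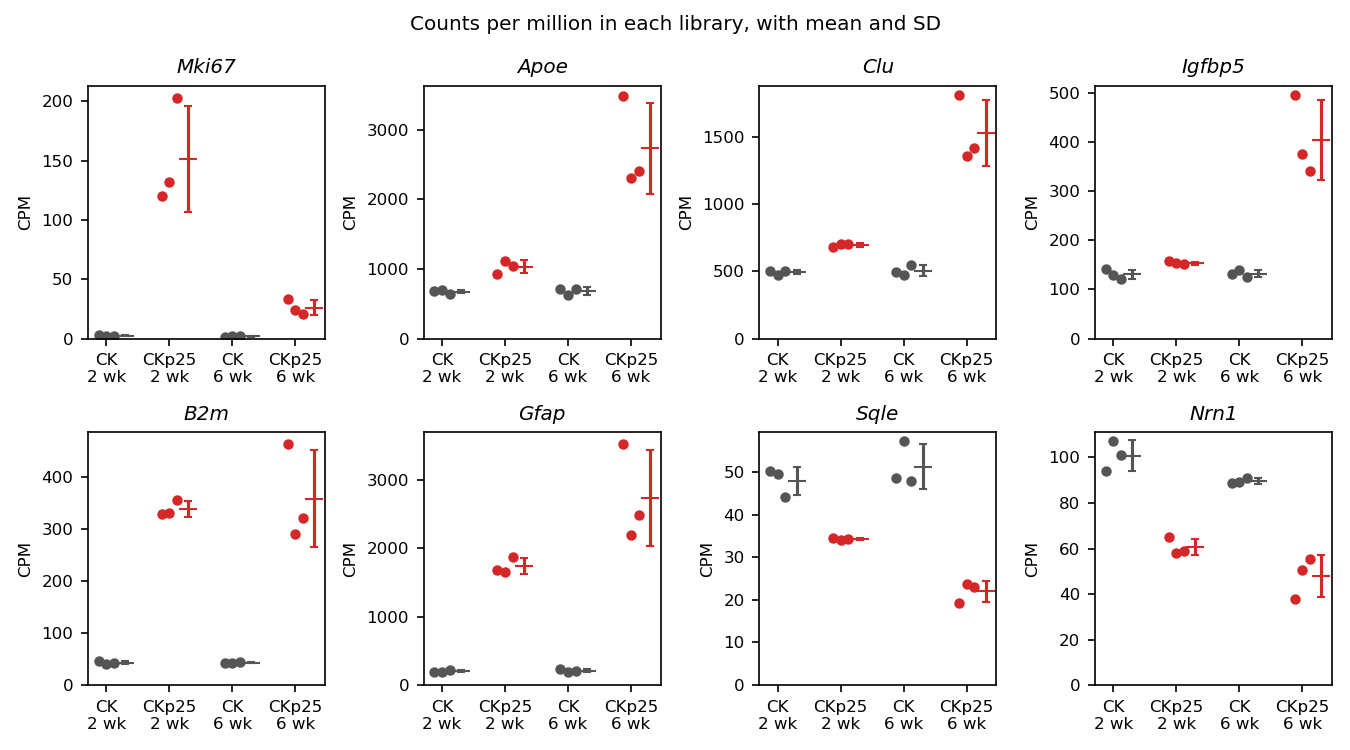
CPM of 8 genes are shown for each library (points, n = 3 per group) with the group mean and SD beside them, CK in grey and CKp25 in red. Mki67 falls from a mean of 152 CPM in CKp25 at 2 weeks to 26.1 at 6 weeks, while Apoe rises from 1029 to 2732.

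Within CK, 6 weeks was compared with 2 weeks as the background of the time course. No gene was called by edgeR, DESeq2 or limma-voom (0, 0 and 0), and 560 of 14457 had an unadjusted p under 0.05 in edgeR. Mki67 was at 2.25 ± 0.421 and 2.11 ± 0.424 CPM, and Apoe at 672 ± 23.6 and 683 ± 53.9. By camera, myelin genes were higher (median 0.16, adjusted p = 0.00804), as were choroid plexus genes (1.42, adjusted p = 0.0421) and heat shock genes (0.14, adjusted p = 0.0297), and early genes were lower (-0.21, adjusted p = 0.0297), with 0 members of each called, also when adjusted over the list alone. All 4 had an adjusted p of 0.958 with an estimated correlation and of 0.939 by fry. The myelin call was lost without CK_2wk_4891, CK_6wk_3938 or CK_6wk_4009 (0.14, 0.13, 0.17), the choroid plexus call without CK_2wk_4891, CK_2wk_4893, CK_6wk_3936, CK_6wk_4009 or CKp25_6wk_3937 (0.93, 0.92, 1.63, -0.02, 1.42), the early gene call without CK_2wk_4891, CK_6wk_3936 or CK_6wk_3938 (-0.14, -0.10, -0.18), and the heat shock call without CK_2wk_4520, CK_2wk_4891, CK_6wk_3936 or CK_6wk_3938 (0.16, 0.13, 0.17, 0.15). Calls were gained by interferon (0.21), thalamus (0.50) and oxidative phosphorylation genes (-0.11) without CK_2wk_4520, by pericyte genes without CK_2wk_4893 (-0.57) and by oxidative phosphorylation genes without CK_6wk_3936 (-0.10). Without a filter on low counts, edgeR called 130 genes, and with CK_2wk_4520 and CKp25_2wk_4518 both left out it called 1 higher and 25 lower.

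Within CKp25, the proliferation genes Mki67, Cenpf and Ccna2 fell from 2 to 6 weeks, and Igfbp5, Clu and Apoe rose. Mki67 fell from 152 ± 44.8 to 26.1 ± 6.60 CPM, the kinetochore gene Cenpf from 28.2 ± 7.34 to 4.37 ± 1.07, and the cyclin gene Ccna2 from 21.0 ± 4.37 to 4.13 ± 0.741. Igfbp5 rose by 1.39 ± 0.11, Clu by 1.13 ± 0.10 and Apoe by 1.41 ± 0.13 (log2, SE). Cell cycle genes were lower in 25 of 26 cases (26 adjusted over the list alone; median -1.44), DNA repair genes in 8 of 16 (12 adjusted over the list alone; median -0.77) and interferon genes in 11 of 24 (13 adjusted over the list alone; median -0.54), with an adjusted p of 0.0628, 0.0628 and 0.265 with an estimated correlation. Astrocyte genes were higher in 9 of 12 cases (9 adjusted over the list alone; median 0.46) and myelin genes in 10 of 12 (11 adjusted over the list alone; median 0.61), with an adjusted p of 0.167 for each with an estimated correlation. Endothelial genes were higher in 7 of 11 (8 adjusted over the list alone; median 0.46) and pericyte genes in 5 of 12 (8 adjusted over the list alone; median 0.74), with an adjusted p of 0.167 and 0.265 with an estimated correlation. Camera called these 7 lists with its preset correlation, at an adjusted p of 2.62e-22 to 9.41e-05, and none held with an estimated one. It also called as higher activated microglia (median 0.45), complement (0.60), reactive astrocyte (0.63), border macrophage (1.2), thalamus (0.61) and inhibitory neuron genes (0.29), and as lower CA pyramidal neuron (-0.18), synaptic vesicle (-0.17), glutamate receptor (-0.26), channel (-0.23), early (-0.65), p53 (-0.44) and cholesterol synthesis genes (-0.47), at an adjusted p of 0.0628 to 0.369 with an estimated correlation. Fry did not call the reactive astrocyte and synaptic vesicle lists (adjusted p = 0.0641 for each). The CA pyramidal neuron call was lost without CK_2wk_4893, CKp25_2wk_4518, CKp25_2wk_4890 or CKp25_6wk_3937 (-0.18, -0.13, -0.16, -0.12). Calls were gained by dentate granule neuron genes without CKp25_2wk_4890, CKp25_2wk_4894, CKp25_6wk_3937 or CKp25_6wk_4008 (-0.46, -0.53, -0.39, -0.55), MHC class II genes without CKp25_2wk_4890 or CKp25_6wk_3940 (2.15, 1.56), oligodendrocyte precursor genes without CKp25_2wk_4894 or CKp25_6wk_3940 (0.19, 0.21), MHC class I and cytokine genes without CKp25_6wk_3937 (-0.21, -0.47) and choroid plexus genes without CKp25_6wk_3940 (1.68). In all, 885 genes were higher and 800 lower at 6 weeks by edgeR. This balance turned with a 2-fold minimum (105 higher, 202 lower), RLE scaling (844, 861), DESeq2 (658, 704) and counts thinned to 50% (578, 584). It also turned without CKp25_2wk_4518 (637, 709), CKp25_2wk_4894 (467, 507) or CKp25_6wk_3940 (965, 1064), and with CK_2wk_4520 and CKp25_2wk_4518 both left out (688, 724). The total of 1685 was 974 without library CKp25_2wk_4894 and 839 without library CKp25_6wk_3937. Lower genes numbered 524 without CKp25_6wk_4008.

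Over both times together, with 6 libraries per genotype, 2816 genes were higher and 2611 lower in CKp25. Higher genes included B2m (3.02 ± 0.10 log2, SE; edgeR adjusted p = 7.83e-12), the interferon-induced Lgals3bp (4.08 ± 0.14) and the lysosomal protease Ctss (3.06 ± 0.11). Lower genes included the neurite growth factor Nrn1 (-0.81 ± 0.08) and the potassium channel gene Kcnh3 (-0.86 ± 0.08).

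Peak lists of the 7 marks were compared between CKp25 and CK at each time, with lists of the same genotype at different times as the background. H3K27ac marks active promoters and enhancers, H3K4me3 promoters, H3K4me1 enhancers, H3K36me3 and H4K20me1 transcribed gene bodies, and H3K27me3 and H3K9me3 repressed chromatin. Of H3K27ac peaks, 68.1% overlapped between CKp25 and CK at 2 weeks, 65.6% at 6 weeks and 68.2% between the CK lists. The shares in that order were 77.1, 76.8 and 79.3% for H3K4me3, 70.2, 68.9 and 72.0% for H3K4me1, and 78.1, 76.7 and 78.6% for H3K36me3. For H4K20me1 they were 76.2, 77 and 79.0%, for H3K27me3 41.6, 46.1 and 46.3%, and for H3K9me3 43.1, 48.3 and 48.8%. Lists held 70236 (H3K9me3, CKp25, 2 weeks) to 269327 peaks (H4K20me1, CK, 2 weeks). Between the CKp25 lists of both times, 68.9% of H3K27ac, 77.8% of H3K4me3, 69.9% of H3K4me1, 78.0% of H3K36me3, 77.1% of H4K20me1, 42.7% of H3K27me3 and 42.6% of H3K9me3 peaks overlapped, the last below both comparisons of genotypes. There is 1 list per group, so no replicate check was possible.

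Regions with strong peaks in both CKp25 lists and no peak in either CK list were counted against the 4 other divisions of a mark's lists. H3K4me3 had 1775 such regions and 496 in the reverse direction, where the other divisions gave 379 to 853, and 40974 regions were strong in all 4 lists. H3K27ac had 2520 and 1335, where the others gave 774 to 1323, and H3K36me3 2153 and 808 (822 to 1219). H4K20me1 had 1442 and 4042 (949 to 1930), and H3K4me1 1918 and 2531 (1262 to 1516). The repressive marks had 490 and 1233 (H3K27me3; 397 to 1558) and 466 and 1565 (H3K9me3; 564 to 1248). With equal numbers of the strongest peaks per list, the H3K4me3 counts were 1176 and 750 (440 to 569) and the H3K27ac counts 1845 and 1490 (754 to 919), so that regions of both directions exceeded the other divisions. With that setting the H3K9me3 counts were 476 and 592 (466 to 582) and the H4K20me1 counts 1633 and 2333 (961 to 1192). The H3K36me3 counts were 1788 and 1140 (762 to 1563), the H3K27me3 counts 686 and 865 (655 to 877), and the H3K4me1 counts 1937 and 2196 (1214 to 1375). With a -log10 p of at least 10, H3K4me3 had 100 regions in CKp25 alone and 2 in CK alone (others 1 to 11), and H3K27ac 56 and 5 (1 to 7). With that limit the direction turned for H4K20me1, with 35 in CKp25 alone and 20 in CK alone (1 to 5). H3K27me3 had 1 and 0 (0 to 3), too few to give a direction.

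Regions found in CKp25 alone, with no peak in either CK list, were ranked by the lower -log10 p of the 2 CKp25 lists. For H3K4me3, the strongest of them lay in mm9 on chromosome 2 from 161336741 to 161337539 (-log10 p of 42.3 at 2 weeks and 30.7 at 6 weeks). The next lay on chromosome 12 from 104679841 to 104682423 (28.9 and 86.1). For H3K27ac, the strongest region found in CKp25 alone lay on chromosome 9 from 3018746 to 3019052 (24.1 and 28.7). The next lay on chromosome 5 from 101064226 to 101067176 (24.7 and 20.3). No filter for repeats or poorly mapped stretches was applied to the lists here, so an alignment artifact was not excluded for any of these regions. Overlap with other marks was counted against strong peaks only (-log10 p of at least 5), in either list of a genotype, so weaker peaks were left out. Of the H3K27ac regions found in CKp25 alone, 43.2% overlapped an H3K4me3 peak of CKp25 and 26.9% one of CK. H3K4me1 peaks overlapped 61.0% of them in CKp25 and 43.2% in CK. Of H3K27ac regions found in CK alone, 66.4% overlapped an H3K4me1 peak of CK and 45.8% one of CKp25, and H3K4me3 peaks overlapped 24.6% in CK and 22.2% in CKp25. Regions strong in all 4 lists overlapped H3K4me3 peaks in 82.3% (CK) and 83.4% (CKp25) of cases, and H3K4me1 peaks in 91.8 and 90.9%. Strong H3K4me3 peaks numbered 59430 and 64675 in CK and 65852 and 70558 in CKp25 at 2 and 6 weeks. Strong H3K4me1 peaks numbered 138908 and 136062 in CK and 128159 and 131778 in CKp25. These list sizes were not equalized here.

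**Figure D3:**
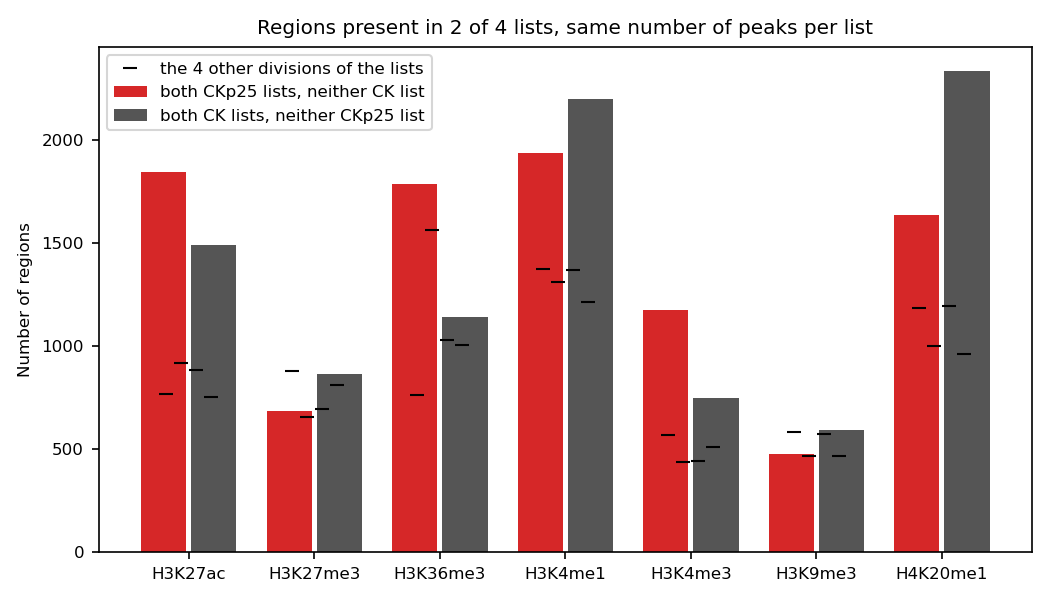
Bars give the number of regions per mark with peaks in both CKp25 lists and neither CK list (red) or the reverse (grey), with the same number of strongest peaks taken from each list. Black dashes give the 4 other divisions of the same lists; for H3K27ac the bars are 1845 and 1490 and the highest dash is 919.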

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

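The tests in this part were chosen only after the results were seen, except the count over all splits of the libraries and the tests of the difference between times.

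The results listed here stood out because the effect of CKp25 differed between 6 and 2 weeks by a test of that difference. Genes that gained, in log2, were Igfbp5 (1.38), Clu (1.10), Apoe (1.39), Ccdc3 (1.53) and Prdx6 (1.00). Genes whose effect was lower at 6 weeks were Plk5 (-1.78), Col6a4 (-4.42), Tex15 (-2.08), Myo5b (-0.82) and Bbc3 (-2.27). CK levels of Plk5 were 7.32 to 9.89 CPM at 2 weeks and 13.2 to 17.2 at 6 weeks. Those of Tex15 were 4.09 to 8.53 and 9.08 to 14.2, and of Col6a4 0.205 to 1.02 and 2.43 to 5.09. Bbc3 was higher in CK too (2.64 to 3.48, then 4.19 to 5.06), and none of these was called for time in CK. In Plk5, Tex15 and Col6a4, all CKp25 libraries lay above CK at 2 weeks and below CK at 6 weeks. Lists with a higher median at 6 weeks were blood leukocyte and border macrophage (1.61), pericyte and meningeal fibroblast (0.91), activated microglia (0.73), complement (0.59), endothelial (0.58), reactive astrocyte (0.51), oligodendrocyte (0.47), astrocyte (0.45) and inhibitory neuron (0.32). In the blood leukocyte and border macrophage list only Mrc1, Cd163 and Lyve1 were tested, so its median does not speak for blood leukocytes. Lists with a lower median were cell cycle (-1.36), DNA repair (-0.64), type I interferon (-0.56), p53 (-0.47), early gene (-0.44), cholesterol synthesis (-0.37), dentate granule neuron (-0.35), glutamate receptor (-0.26), voltage-gated channel (-0.22) and synaptic vesicle (-0.18). These list calls rest on camera's preset correlation, and with an estimated correlation the adjusted p was 0.117 to 0.522. By fry 12 of the 19 calls were lost, at an adjusted p of 0.101 to 0.274. By leaving out a library, complement lost its call without CK_2wk_4520 (0.34) or CKp25_6wk_3937 (0.34), the border macrophage list without CK_2wk_4520 (0.76), synaptic vesicle without CK_2wk_4520 (-0.16) or CKp25_6wk_3937 (-0.10), early genes without CKp25_2wk_4518 (-0.27) or CK_6wk_4009 (-0.34), and dentate granule neuron without CK_2wk_4891 (-0.37), CKp25_2wk_4518 (-0.27), CK_6wk_3938 (-0.30), CK_6wk_4009 (-0.33) or CKp25_6wk_3940 (-0.24). Other lists gained a call, namely thalamus without CK_2wk_4893 (0.56), CKp25_2wk_4518 (0.30), CKp25_2wk_4890 (0.47), CKp25_6wk_3940 (0.45) or CKp25_6wk_4008 (0.28), and oxidative phosphorylation without CK_2wk_4520 (0.14), CKp25_2wk_4890 (0.13), CK_6wk_3936 (0.10) or CKp25_6wk_3937 (0.13). So did homeostatic microglia without CKp25_2wk_4894 (0.24), erythrocyte without CK_6wk_4009 (0.93) and MHC class I without CKp25_6wk_3937 (-0.18).

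A chance division of these libraries can be excluded for the genotype effect over both times, where the real split called 5427 genes. It was the only 1 of 100 splits to reach that count, and the highest other split called 24. The labels do not say that libraries are animals, so chance between animals was not excluded by this. By the count over all splits, a chance division was not excluded for the difference between times. There, 9 of 100 splits called at least the real 80 genes and the highest other called 932. Of the 8 other splits that did so, 7 left the real time groups within CKp25 intact and called 167 to 932 genes, so they still held the time effect within CKp25 and did not break the grouping. Of the 92 splits that broke it, 1 reached 80, with 84 genes, and their median was 0. This division of the splits was not part of the planned rule. Splits that mix the times of CKp25 move its time effect into the spread within groups, which lowers their calls. Their low counts therefore do not exclude chance for the difference between times. The remaining contrasts allow 10 splits, too few for a share under 0.05. Their real counts and highest others were 2833 and 1 at 2 weeks, 4811 and 0 at 6 weeks, 1685 and 4 for time in CKp25 and 0 and 2 for time in CK.

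Immune lists were higher in CKp25 at both times by camera with its preset correlation. With an estimated correlation none of their calls at 6 weeks held, nor did that of MHC class II genes at 2 weeks. By fry, 23 of camera's 24 list calls at 6 weeks held. A lower share of neurons would raise glial lists alike, but the homeostatic microglia score rose by 1.58 ± 0.136 log2 (SE) more than the oligodendrocyte score at 2 weeks. More microglia with unchanged expression per cell would raise both microglia lists alike, but activated genes rose by 0.947 ± 0.0812 more than homeostatic ones over both times (exact permutation p = 0.005, the smallest that 400 permutations can give). A lower share of neurons therefore fails as the whole cause of the rise in homeostatic microglia genes at 2 weeks. The other immune lists were not compared with oligodendrocyte genes. More microglia at unchanged expression fails as the whole cause only if the activated genes are read from microglia alone, which bulk tissue did not show. A change of state in microglia together with a rise in their number may remain as a hypothesis.

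The cell cycle score fell by 1.41 ± 0.171 log2 (SE) from 2 to 6 weeks in CKp25, and camera's call of the difference from CK was lost with an estimated correlation (adjusted p = 0.117). In CK, whose library numbers interleave with those of CKp25 at each time, it changed by -0.0494 ± 0.171, and the labels give no batch to test. With choroid plexus genes as a covariate the median difference of the list was -1.41, against -1.36 without it, so carried-over choroid plexus does not account for it. A wave of proliferation that had partly passed by 6 weeks may be a hypothesis, and which cells divided was not tested.

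Synaptic vesicle and glutamate receptor genes were lower in CKp25 at both times by camera with its preset correlation. These list calls were lost with an estimated correlation at both times. Dilution by glial RNA would lower inhibitory neuron genes equally, but the synaptic lists fell by 0.70 ± 0.0636 log2 (SE) more than these at 6 weeks. At 2 weeks they fell by 0.198 ± 0.0636 more, short of the 0.3 set for this test, and inhibitory neuron genes were lower too (median -0.13, camera adjusted p = 0.0535), so dilution stays open there. The choice of scaling moved the lists' median by 0.0154 at most at 2 weeks and 0.0246 at 6 weeks. Loss of excitatory neurons and lower expression in surviving ones both may contribute, and bulk tissue did not separate them.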

How the results depend on the processing

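The block on nearest library numbers, the covariates for choroid plexus genes and for reads with several alignments, leaving out 2 libraries together, the thinned counts and the p-value limits for peaks were chosen only after the results were seen, and the other alternatives were planned. The cause was not tested for any change below unless one is named.

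Among gene counts, the totals of CKp25 against CK at 2 and 6 weeks and over both times stayed within 1.5 times under other scalings, filters and tools. The 80 genes whose effect differed between times became 693 without a filter on low counts, 219 with DESeq2, 302 with choroid plexus genes as a covariate, 301 with the share of reads with several alignments as a covariate and 544 with nearest library numbers as a block, and these included 80, 77, 80, 72 and 80 of the 80. With libraries CK_2wk_4520 and CKp25_2wk_4518 both left out, time in CK gave 26 genes. Without the filter it gave 130, and the prior degrees of freedom of edgeR, 8.73 with it, became infinite. The labels share no replicate numbers between groups, and deviations of nearest-number pairs correlated at 0.383, 0.208, 0.0800, -0.0407, 0.312 and 0.282, a hint from the data and not the design. The block was not fitted to time contrasts, since the pairs lie within a time. Stricter thresholds call fewer genes by construction. An adjusted p under 0.01 left 1660 genes at 2 weeks, 3147 at 6 weeks, 11 for the difference and 728 for time in CKp25. A minimum of 2-fold left 993, 1259, 30 and 307, and 1108 over both times. The Pearson r of 0.809 between times was 0.767 with a filter of 1 CPM in 3 libraries and 0.842 over called genes.

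Leaving out each library gave 1806 to 3056 genes at 2 weeks, 3501 to 5054 at 6 weeks, 24 to 204 for the difference, 0 to 0 for time in CK, 839 to 2029 for time in CKp25, 4836 to 5673 over both times, and an r of 0.767 to 0.796. Depth was tested by thinning all counts to 50%, which left 1889 genes at 2 weeks and 3595 at 6 weeks. Of the calls at 2 weeks, 53.2% of those under 6 CPM, 71.4% of those from 6 to 30 CPM and 63.1% of those over 30 CPM were kept, and at 6 weeks 45.7, 70.5 and 78.8%. Leaving out a library kept at least 81.1, 70.01 and 50.6% of the calls at these levels at 2 weeks, so by these lowest shares its losses there were not greatest among low genes. The 2-week calls had a median absolute log2 fold change of 2.16, 0.871 and 0.353 at these levels. The shares therefore do not compare levels at a like size of change. At 6 weeks it kept at least 70.5, 70.1 and 73.1%. Without CK_6wk_3938 the shares at 6 weeks were 72.3, 75.7 and 78.0%, with the greatest loss among low genes.

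With equal numbers of strongest peaks, an overlap of 50% of the peak, and a -log10 p of at least 5, the shared percentages at 2 weeks were 68.5, 55.1 and 70.1 for H3K27ac, 42.4, 28 and 42.1 for H3K27me3, 78.5, 65.3 and 79.1 for H3K36me3, and 69.9, 55.2 and 68.3 for H3K4me1. They were 78.7, 68.3 and 80.2 for H3K4me3, 42.4, 29.1 and 35.7 for H3K9me3, and 76.7, 60.8 and 74.8 for H4K20me1. At 6 weeks they were 65.9, 52.7 and 67.1 for H3K27ac, 45.2, 31.9 and 44.8 for H3K27me3, 77, 63.5 and 76.9 for H3K36me3, and 54.2 and 67.0 for H3K4me1 under the last 2 settings. They were 78.1, 68.7 and 78.9 for H3K4me3, 46.2, 34.5 and 42.7 for H3K9me3, and 76.5, 63.2 and 75.7 for H4K20me1.

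Regions in CKp25 alone and in CK alone numbered, at a -log10 p of at least 10, 56 and 5 for H3K27ac, 1 and 0 for H3K27me3, 19 and 6 for H3K36me3, 2 and 5 for H3K4me1, 100 and 2 for H3K4me3, 1 and 8 for H3K9me3, and 35 and 20 for H4K20me1. Equal numbers of peaks gave 1176 and 750 for H3K4me3, and 592 and 2333 in CK alone for H3K9me3 and H4K20me1. Among called gene lists and named genes, no value changed sign in these fits except the choroid plexus median for time in CK, 1.42, which was -0.02 without CK_6wk_4009. DESeq2 gave no adjusted p for Col6a4 in the difference between times, so that call was not compared. A q-value limit was not run, since that column holds no q-values, nor were marks at promoters.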

Other observations

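The list tests in this part were planned, and the chromosome shares and Ttr values were chosen only after they were seen.

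In the blood leukocyte and border macrophage list, 3 of 16 genes were tested, and 3 of 3 were higher at 6 weeks (3 adjusted over the list alone; median 1.77) while 0 of 3 were at 2 weeks (median 0.17). The genes tested were Mrc1, Cd163 and Lyve1, and the list's T cell genes were not among them. Mrc1, the mannose receptor of border macrophages, rose from 4.44 ± 1.15 to 15.4 ± 5.56 CPM (SD, n = 3) at 6 weeks. Camera did not call this list at 6 weeks (adjusted p = 0.0549, and 0.274 with an estimated correlation), though fry did (adjusted p = 0.00719). Camera called it without library CK_2wk_4520 (1.77), CK_2wk_4893 (1.77), CKp25_2wk_4890 (1.77), CK_6wk_3936 (1.98) or CKp25_6wk_3940 (2.05). Lyve1 was not called without any 1 of CK_6wk_3936, CK_6wk_3938, CK_6wk_4009, CKp25_6wk_3937 or CKp25_6wk_4008 (2.20, 1.98, 1.87, 1.71, 1.90), nor Cd163 without CK_6wk_3938, CK_6wk_4009, CKp25_6wk_3937 or CKp25_6wk_4008 (0.92, 1.2, 1.2, 1.09) or by DESeq2 (1.18). Oligodendrocyte precursor genes were higher in 1 of 7 cases at 2 weeks (2 adjusted over the list alone; median 0.20) and 3 of 7 at 6 weeks (3 adjusted over the list alone; median 0.25), and camera called the list at neither time, while fry called it at 6 weeks (adjusted p = 0.0417).

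Inhibitory neuron genes went both ways at 6 weeks, with 3 of 13 higher and 1 lower (3 and 1 adjusted over the list alone; median 0.19; camera adjusted p = 0.23). At 2 weeks 2 of 13 were lower (2 adjusted over the list alone; median -0.13; camera adjusted p = 0.0535). The list was called at 2 weeks without CK_2wk_4891 (-0.15), CKp25_2wk_4518 (-0.17), CKp25_2wk_4890 (-0.14), CKp25_6wk_3937 (-0.13) or CKp25_6wk_3940 (-0.12). Pvalb, of fast-spiking interneurons, was higher at 6 weeks by 0.58 ± 0.17 log2 (SE), a call lost without CKp25_6wk_3940 (0.39), with reads of several alignments as a covariate (0.47) and with counts thinned to 50% (0.45), and the neuropeptide gene Cck differed by -0.66 ± 0.10. Thalamus genes were higher in 2 of 6 cases at 6 weeks (2 adjusted over the list alone; median 0.52), with a camera adjusted p of 0.0389, an adjusted p of 0.279 with an estimated correlation, and no call without CK_6wk_3938 (0.44) or CKp25_6wk_3937 (0.30). At 2 weeks 1 was higher and 1 lower (median 0.23). Striatum genes had 1 higher and 0 lower of 8 at 2 weeks and 1 of each at 6 weeks (medians 0.08 and -0.21), and erythrocyte genes 0 of 3 at both (medians -0.83 and -0.28). The erythrocyte list was called lower at 2 weeks without CKp25_2wk_4894 (-1.16). Oxidative phosphorylation genes were lower in 2 of 22 cases at 2 weeks (2 adjusted over the list alone; median -0.20) and 1 of 22 at 6 weeks (0 adjusted over the list alone; median -0.12), with camera adjusted p of 0.000126 and 0.0309. With an estimated correlation the adjusted p was 0.417 and 0.564, and the 6-week call was lost without CK_6wk_3936 (-0.09), CK_6wk_4009 (-0.10) or CKp25_6wk_3937 (-0.08). Heat shock and unfolded protein genes had 2 higher and 2 lower of 14 at each time (3 and 2, then 2 and 2, adjusted over the list alone; medians 0.04 and -0.09). The stress-induced factor Atf3 was higher by 1.93 ± 0.40 and 2.58 ± 0.41 log2 (SE).

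Ttr varied widely within each group. It was at 871, 15.1 and 7.52 CPM in CK libraries CK_2wk_4520, CK_2wk_4891 and CK_2wk_4893, and at 1053, 6.49 and 298 in CKp25 libraries CKp25_2wk_4518, CKp25_2wk_4890 and CKp25_2wk_4894. At 6 weeks it was at 590, 20.6 and 2244 in CK libraries CK_6wk_3936, CK_6wk_3938 and CK_6wk_4009, and at 1037, 6.44 and 1820 in CKp25 libraries CKp25_6wk_3937, CKp25_6wk_3940 and CKp25_6wk_4008. The choroid plexus list had medians of 0.59 at 2 weeks and 0.32 at 6 weeks.

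Repressive marks had many peaks on chromosome X. Its share of H3K9me3 peaks was 40.1% in CK and 40.4% in CKp25 at 2 weeks, and 42.0% and 35.2% at 6 weeks. For H3K27me3 the shares were 26.9, 27.2, 25.5 and 22.8% in that order. For H3K27ac they were 0.838, 0.860, 0.884 and 0.872%. With 1 list per group these differences have no replicate check.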
